A study of Mus musculus with 6 samples.

How the data were processed

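RNA sequencing was used to measure transcript levels in 6 samples of sorted mouse leukaemic blasts, 3 wild-type (WT) and 3 carrying an inducible Stat3β transgene (Stat3β TG). Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, FastQC, STAR and DESeq2 were used with the mouse build GRCm38 (mm10). Versions, the gene counter, its handling of strand, the annotation release and any filter before deposit are not given in the sources used here. The values the authors deposited are gene-level normalized counts, a signal that is never negative, with 1 column per library and NCBI Entrez gene IDs. The values themselves show how they were scaled: in each library the values were whole multiples of 1 step. Dividing by that step gave a whole number, within 0.001, for 100% of 146724 values, with a largest distance of 7.57e-10. Each step was therefore taken as the worth of 1 read, and whole reads were recovered.

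Of 24454 gene IDs, 24376 had a symbol in the NCBI RefSeq gene table of GRCm38.p6, from which symbols and coordinates were taken. The other 78 had none, and 13 of them were among the genes tested. The recovered reads per library ranged from 21809788 to 51934498, and Stat3β TG 1 and Stat3β TG 3 were the deepest. A count of 3 reads, the limit that a count of 0 allows, equalled between 1.69 and 4.22 normalized counts in these libraries, and covers counting error only. No pair of libraries agreed within sampling noise, with a chi-square per gene of 65.9 to 225 over all pairs, so every library was counted as 1 sample. Genes with near-identical copies can share or lose reads. The alpha- and beta-globin genes Hba-a1, Hba-a2, Hbb-b1, Hbb-b2, Hbb-bs and Hbb-bt were listed at 0 in all 6 libraries, and Gapdh, which has many processed copies, averaged 751 normalized counts. Values of paralog families, histone genes and the antisense pair Xist and Tsix are therefore uncertain.

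The design, the gene lists, the genes to be named and most alternatives were fixed before the data were examined. Genes with a normalized count of at least 10 in at least 3 libraries were tested, which left 12642. Values were analysed as log2(normalized count + 1). The pseudocount pulls fold changes of low genes toward 0, but they are differences of mean log values and can exceed the ratio of the group means where 1 library is near 0. For Klrd1 the log2 fold change was 2.59 on this scale, 1.81 by edgeR and 1.85 by DESeq2. The test was limma 3.58.1 with a mean-variance trend and robust moderation in R 4.3.3, with the group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. On the recovered reads, edgeR 4.0.16 (quasi-likelihood, TMM factors) and DESeq2 1.42.0 (Wald test) were run as alternatives, and an adjusted p that DESeq2 left missing stayed missing. The edgeR biological coefficient of variation was 0.318.

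There were 35 gene lists, of which 33 had at least 5 tested members. Their 727 entries were matched by symbol (684) or by an unambiguous older symbol (23), and 20 were not matched. The mitochondrially encoded list had 0 members in the table, and the B lineage list had 4 tested members. Each list was tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 33 lists, and again with the correlation estimated per list. The rotation test fry was run beside it. For the 9 lists of other cell types, the mean log2 level per library was compared between groups by an exact two-sided permutation test over 20 assignments, whose smallest possible p is 0.1.

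Genes were named by a rule. Stat3 was always named. The rule then took up to 12 genes in each direction among those past the adjusted threshold, with a mean of at least 50 in the higher group and no overlap between groups, and 0 genes qualified. Up to 4 members of each list with the smallest p could also be named. Genes named because DESeq2 called them, together with S100a8, S100a9, Ngp, Chil3, Il1r2, Ddx3y, Kmt2a, Mllt3 and the genes that escape X inactivation, fall outside the rule unless they also belong to it, and were chosen after their values were seen. Some results under the rule are not reported here.

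The scripts were tested on simulated counts for the 6 libraries, with 100 genes changed 2-fold and 100 changed 4-fold. With gene-wise dispersions estimated from the data, over 12480 genes, limma called 30 and 81 of them and 16 unchanged genes. There edgeR called 29 and 80 with 17 unchanged genes, and DESeq2 called 56 and 91 with 62 unchanged genes, which made 29.7% of its calls. With a common dispersion, over 12545 genes, limma called 11 and 87 with 1 unchanged gene, edgeR 13 and 93 with 3, and DESeq2 19 and 94 with 9. False calls of DESeq2 were thus above the nominal 5% in both simulations, and those of limma and edgeR in the first. In a simulation of the list test over 12642 genes, a list of 20 members moved 2-fold had an adjusted p of 4.48e-14 by camera, 0.0314 with an estimated correlation and 0.0183 by fry, and 0 of 32 other lists were called. Genes were drawn independently there, so it cannot show how often camera calls lists whose members vary together. In the data the estimated correlation was 0.371 for mature neutrophil genes and 0.608 for MYC targets.

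The count of genes past the threshold was recomputed under 22 alternatives. They cover pseudocounts, filters, scaling, the variance model, sample weights, a replicate block, other tests and leaving out each of the 6 libraries. Of these, 3 were chosen after seeing the data: a term for the pattern of sex-linked genes, reads thinned to equal totals, and leaving out both WT 2 and WT 3. All 12 alternatives of the DESeq2 count were also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.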

Results

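The study asked how Stat3β, a shorter splice form of the transcription factor STAT3, bears on acute myeloid leukaemia driven by the fusion oncogene MLL-AF9. Fetal liver cells of wild-type mice or of littermates with an Mx1-Cre-inducible Stat3β transgene, on a C57BL/6 background, were transduced with an MLL-AF9 retrovirus. They were transplanted into NSG mice, which lack T, B and NK cells of their own. The recipients were given poly(I:C), which induces Mx1-Cre, 4 weeks after transplantation. Leukaemic blasts were sorted by the Venus reporter at 6 weeks, and their RNA was sequenced. There were 3 WT and 3 Stat3β TG libraries. The recovered reads came to 26805344, 21809788 and 21847953 for WT 1 to 3, and to 46579680, 24733256 and 51934498 for Stat3β TG 1 to 3. Between 14917 and 15966 genes had at least 1 read per library. The sample labels do not say that the replicates came from separate donors, so each p measures only the spread between these samples.

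Stat3 itself was abundant in both groups and did not differ past the test. Its level was 11683 ± 4087 normalized counts in WT and 9670 ± 1555 in Stat3β TG (SD, n = 3 each), with the WT libraries at 8058, 16112 and 10879 and the Stat3β TG libraries at 11129, 9846 and 8034. The gene (Entrez 20848) lies on chromosome 11 at 100885098 to 100939540 on the minus strand (GRCm38). The log2 fold change of Stat3β TG over WT was -0.23 with a standard error of 0.26 (limma adjusted p = 0.771). A gene-level value sums both splice forms, so it does not measure Stat3β by itself. The sign of the difference depended on WT 2, the library with the highest Stat3 value, without which the log2 fold change was 0.03.

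The libraries did not separate by group alone. WT 1 lay with the Stat3β TG libraries on the first principal component, which held 47.4% of the variance, at -38.3 against -31.4, -16.3 and -28.2, while WT 2 and WT 3 lay at 64.4 and 49.7. The Spearman correlation of WT 1 with the Stat3β TG libraries was 0.982 to 0.984, against 0.951 with WT 2 and 0.964 with WT 3. Genes of the sex chromosomes split the libraries in another way. Xist, the RNA that silences the inactive X chromosome, had 42699 and 45196 normalized counts in WT 1 and WT 3, and 835 in WT 2, against 71.6, 25.9 and 19.1 in Stat3β TG. Xist reads may include its antisense partner Tsix, since the handling of strand is not stated. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 58.8 and 71.8 in WT 1 and WT 3, to 11012 in WT 2, and to between 8782 and 9465 in Stat3β TG. All 5 genes passed adjusted over the list alone. Without 1 library other than WT 2, only Xist passed on that scale, and without WT 2 all 5 also passed over all genes.

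**Figure D1:**
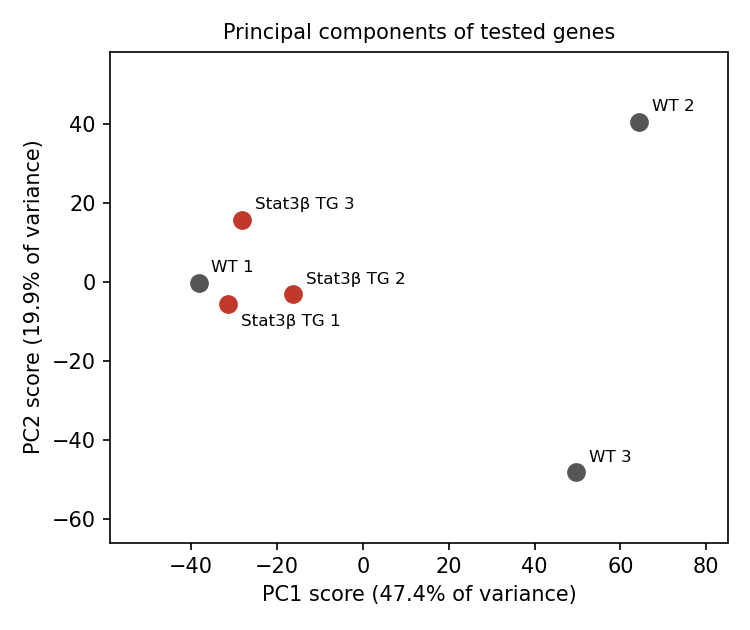
Each point is a library placed by its scores on the first and second principal components (arbitrary units) of log2(normalized count + 1), for 3 WT and 3 Stat3β TG libraries. WT 1 lies at -38.3 on the first component, beside the Stat3β TG libraries, while WT 2 and WT 3 lie at 64.4 and 49.7.

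**Figure D2:**
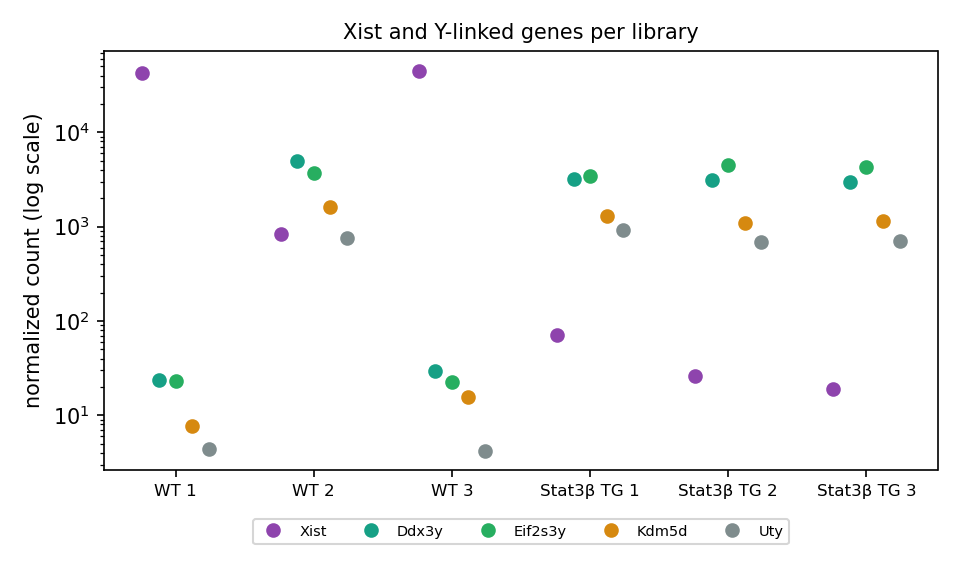
Normalized counts on a log axis of Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with 1 point per gene in each of the 6 libraries. Xist is at 42699 and 45196 in WT 1 and WT 3 and at 835 in WT 2, whose Y-linked genes sum to 11012.

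Over all genes, few differences between Stat3β TG and WT blasts stood out from the spread within groups. The clearest was Fpr2, a formyl peptide receptor of phagocytes (chromosome 17, 17887824 to 17893952, plus strand), at 307 ± 52.98 normalized counts in WT and 1076 ± 79.0 in Stat3β TG (SD, n = 3 each), 3.52-fold higher by limma's estimate. Its neighbour Fpr1 was at 136 ± 52.7 and 596 ± 264, and Lif, which encodes a cytokine acting through STAT3, at 1185 ± 730 and 171 ± 84.3. The limma test passed 0 of 12642 genes, with 771 at an unadjusted p under 0.05 (450 higher and 321 lower in Stat3β TG) where 632.1 would fall by chance. The smallest adjusted p was 0.294, that of Fpr2. On the recovered reads edgeR passed 0 genes with 777 at an unadjusted p under 0.05, and DESeq2 passed 17, of which 9 were higher and 8 lower, with 970. The groups did not overlap in 1364 genes, 10.8% of those tested, where chance gives 10%. Leaving out WT 1 raised the limma count to 296 (200 higher) and the DESeq2 count to 2012. Without WT 2 limma passed 5 genes, which were Xist and the 4 Y-linked genes, and DESeq2 passed 38; DESeq2 passed 33 without WT 3 and 35 without Stat3β TG 3. With a term for the sex-linked pattern, chosen after seeing the data, limma passed 2 genes and DESeq2 954. Because WT 1 and WT 3 carry the pattern that no Stat3β TG library has, that fit compares Stat3β TG with WT 2 alone, an arm of 1 library.

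The 17 genes that DESeq2 called included receptors, a cytokine and a transcription factor among others, and no shared function was tested. Besides Fpr2 (DESeq2 adjusted p = 1.28e-11) and Fpr1 (adjusted p = 0.00227), those higher in Stat3β TG were Cd177, a neutrophil surface protein (3850 ± 990 in WT, 11017 ± 4510 in Stat3β TG; SD, n = 3 each), and Tlr7, an endosomal receptor for RNA (194 ± 40.5 and 458 ± 60.6). Ifnlr1, a receptor for type III interferons, stood at 103 ± 38.9 and 351 ± 128, and the cystatin gene Stfa2 at 2710 ± 823 and 6909 ± 2263. Stfa2 has near-identical neighbours, so its value is uncertain. Mansc1, Clstn3 and Mtus2 were also higher. Among those lower in Stat3β TG, Lif had a DESeq2 adjusted p of 0.000135. Prg2, a granule protein of eosinophils and their precursors, had 0.00182, at 24537 ± 14635 in WT and 5058 ± 1730 in Stat3β TG. It was at 36893 and 28343 in WT 1 and WT 3 but at 8375 in WT 2, near the 7055 of Stat3β TG 1. Much of its difference thus goes with the split of the libraries by sex-linked genes. Egr2, a zinc finger transcription factor, was at 224 ± 38.4 and 59.5 ± 24.4, and the nuclear RNA Malat1 at 31809 ± 9696 and 12359 ± 3324. Zfp820, Cgnl1, Shd and Xist completed the 17. Shd was at 14.1, 543 and 131 in WT 1 to 3, and WT 1 lay within the Stat3β TG range of 8 to 25.9. Cgnl1 was at 505 in WT 1, near the 438 of Stat3β TG 2, and at 2588 and 4216 in WT 2 and WT 3. Xist follows the split of sex-linked genes given above, at 42699 and 45196 in WT 1 and WT 3 but 835 in WT 2. Its call, and how stable it was, cannot be read as a difference of the group apart from that split. By limma every one of these except Fpr2 had an adjusted p of 0.668, and 4 of the 17 (Fpr2, Lif, Zfp820 and Xist) were called by DESeq2 under all of its 12 alternatives.

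**Figure D3:**
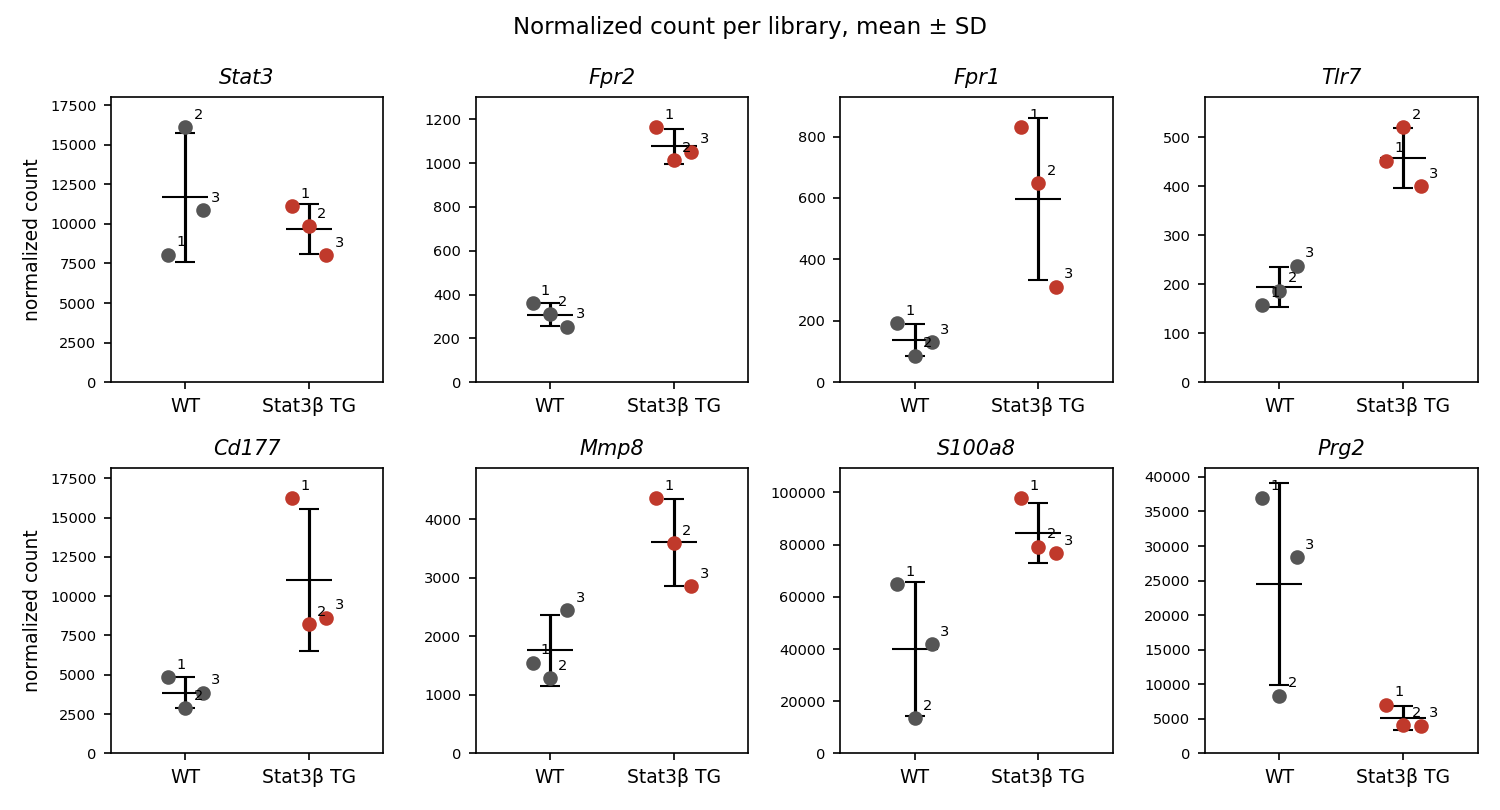
Normalized counts per library of Stat3, Fpr2, Fpr1, Tlr7, Cd177, Mmp8, S100a8 and Prg2 in WT and Stat3β TG, with 1 numbered dot per replicate and bars for mean ± SD (n = 3 each), on axes from 0. Fpr2 lies between 253 and 359 in WT and at or above 1012 in Stat3β TG.

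Genes of mature neutrophils had the smallest camera p of the 33 lists at the preset correlation, and were higher in Stat3β TG. Of 20 tested members 19 were higher, with a median log2 fold change of 1.04 (2.06-fold), and the list was called by camera (adjusted p = 1.72e-09). With an estimated correlation its adjusted p was 0.835. Camera called 5 lists in the real grouping. Each of the 10 splits of the libraries into groups of 3, the real one included, called at least as many. The collagenase gene Mmp8 was at 1764 ± 608 normalized counts in WT and 3606 ± 749 in Stat3β TG (SD, n = 3 each), Wfdc21 at 324 ± 137 and 823 ± 46.2, and S100a8, a calcium-binding protein of neutrophils and monocytes, at 40087 ± 25659 and 84528 ± 11505. In 10 members the unadjusted p was under 0.05, and in 7 the groups did not overlap, where chance gives 10% of genes over both directions. Adjusted over the list alone, 4 members rose (Cd177, Wfdc21 and Mmp8, each with a limma adjusted p of 0.0259, and Stfa2l1, with 0.0476). This count was 11 without WT 1, 2 without WT 2, 1 without Stat3β TG 1, 1 without Stat3β TG 2 and 10 without Stat3β TG 3. The mean log2 level of the list per library was 12.51, 11.48 and 12.03 in WT and 13.49, 12.996 and 12.72 in Stat3β TG (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). WT 2, the library with Y-linked reads in its group, had the lowest mean. Leaving out each library in turn kept the camera call in 6 of 6 cases.

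Camera at the preset correlation also called genes of monocytes and macrophages higher as a set. Of 26 tested members 21 were higher, with a median log2 fold change of 0.61 (camera adjusted p = 0.00258). The adjusted p with an estimated correlation was 0.835. The lysozyme gene Lyz2 was at 13323 ± 7008 normalized counts in WT and 40265 ± 22554 in Stat3β TG (SD, n = 3 each), and Clec4a3, a C-type lectin, at 187 ± 160 and 544 ± 238. Lyz1 and Lyz2 are near-identical, so their separate values are uncertain. No member passed adjusted over the list alone (0 by limma, with 5 at an unadjusted p under 0.05), and 7 passed without WT 1. The mean log2 level was 11.55 in WT 1, near the Stat3β TG values of 11.52, 11.44 and 11.89, and 10.67 and 10.66 in WT 2 and WT 3, the libraries apart on the first principal component (exact permutation p = 0.3). Without WT 2 and WT 3 the median was -0.05, and with the sex-linked term, which sets Stat3β TG against WT 2 alone, it was 0.75 (camera adjusted p = 0.0577).

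Camera at the preset correlation called replication-dependent histone genes and targets of MYC lower in Stat3β TG. Among 20 histone genes 18 were lower, with a median log2 fold change of -0.44 (camera adjusted p = 0.00108; adjusted p = 0.835 with an estimated correlation). H2bc6 was at 157 ± 15.0 normalized counts in WT and 61.9 ± 10.7 in Stat3β TG, and H2ac6 at 54.1 ± 1.88 and 23.3 ± 15.0 (SD, n = 3 each). Histone genes resemble each other, and their transcripts lack a poly(A) tail, so these values are uncertain. Among 24 MYC targets and ribosome biogenesis genes 22 were lower, with a median log2 fold change of -0.20 (camera adjusted p = 0.00194; adjusted p = 0.835 with an estimated correlation). Odc1, the rate-limiting enzyme of polyamine synthesis, was at 4609 ± 1875 and 1833 ± 645, and was the 1 member with an unadjusted p under 0.05. WT 3 had the highest MYC list mean, 12.31 against 11.70 and 11.86 in WT 1 and WT 2 and 11.70, 11.70 and 11.77 in Stat3β TG. The call was lost without it (median -0.03, camera adjusted p = 0.540), and without both WT 2 and WT 3 (median 0.06, 0.490). With the sex-linked term, and so against WT 2 alone, the adjusted p was 0.203 for histones and 0.443 for MYC targets. The fry test for change in either direction called the histone list (adjusted p = 0.0116).

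Other proliferation and energy genes did not pass in the fit with the group as the only term. Of 30 cell cycle genes 18 were lower and 12 higher (camera adjusted p = 0.0702), and the 4 members with an unadjusted p under 0.05 were all lower. Cdc20, an activator of the anaphase-promoting complex, was at 4544 ± 583 normalized counts in WT and 3230 ± 281 in Stat3β TG, and the mitotic kinase gene Cdk1 at 6357 ± 317 and 4720 ± 474 (SD, n = 3 each). Of 33 nuclear-encoded genes of oxidative phosphorylation 27 were lower, with a median log2 fold change of -0.12 (camera adjusted p = 0.0702). Ribosomal proteins were lower in 30 of 42 members (camera adjusted p = 0.318). The cell cycle list was called lower without WT 2 (adjusted p = 9.91e-08) or Stat3β TG 3 (0.0246), and without both WT 2 and WT 3 (5.24e-09), and its median was 0.05 without WT 1 (0.851). Oxidative phosphorylation was called lower without WT 2 (0.0445), Stat3β TG 2 (0.00680) or Stat3β TG 3 (0.000675), and its median was 0.04 without Stat3β TG 1 (0.698). With all libraries and the replicate block, oxidative phosphorylation was also called lower. Ribosomal proteins were called lower without WT 1 (0.0496) or Stat3β TG 2 (0.0268). Their median was 0.02 without WT 3 and 0.03 without Stat3β TG 1, and they were called higher without both WT 2 and WT 3 (median 0.14, adjusted p = 0.00771).

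Genes that STAT3 is known to induce went in both directions. Of 19 tested STAT3 target genes 9 were higher and 10 lower, with a median log2 fold change of -0.07 and a mean of 0.03 (camera adjusted p = 0.854). Lcn2, which encodes lipocalin 2, had a log2 fold change of 0.83, while Bcl3, an atypical IκB protein, was at 1523 ± 1212 normalized counts in WT and 558 ± 24.2 in Stat3β TG (SD, n = 3 each). In the list of JAK-STAT and cytokine receptor genes 19 of 32 were higher (camera adjusted p = 0.586). It held Socs1, a feedback inhibitor of JAK signalling, at 398 ± 297 in WT and 121 ± 45.1 in Stat3β TG. It also held the receptors for GM-CSF and G-CSF, with Csf2ra at 15560 ± 3525 and 23530 ± 1427 and Csf3r at 3920 ± 1433 and 6478 ± 1179. No single gene passed in either list, over all genes or adjusted over the list alone (0 by limma, with 3 at an unadjusted p under 0.05 in each). Without WT 1, 5 STAT3 targets and 8 JAK-STAT genes passed over their lists alone. Without WT 2 and WT 3, which leaves 1 WT library that is assumed to vary like the others, the STAT3 target list (median 0.27, camera adjusted p = 0.0441) and the JAK-STAT list (median 0.11, 0.0258) were called higher.

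Interferon-stimulated, antigen presentation and inflammatory genes were not called with all libraries. Of 33 interferon-stimulated genes 22 were higher, with a median log2 fold change of 0.37 (camera adjusted p = 0.141). Oas2, an antiviral enzyme that synthesizes oligoadenylate, was at 280 ± 130 normalized counts in WT and 542 ± 224 in Stat3β TG, and Eif2ak2, the RNA-activated kinase PKR, at 1687 ± 178 and 1264 ± 151 (SD, n = 3 each). MHC class I genes were higher in 5 of 15 (camera adjusted p = 0.530) and MHC class II genes in 8 of 12 (0.434). Of 23 NF-κB and inflammatory cytokine genes 17 were higher (0.211). The interferon list was called without WT 1 (0.00728), MHC class I without Stat3β TG 3 (0.00976) and NF-κB without WT 2 (5.37e-05). Without WT 2 and WT 3 the interferon median was -0.28 (camera adjusted p = 0.00804) and the NF-κB median 0.23 (0.0458).

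The MLL-AF9 leukaemia programme was not called with all libraries. Of 21 tested members 9 were higher and 12 lower, with a median log2 fold change of -0.02 and a mean of 0.08 (camera adjusted p = 0.860). Mecom, a zinc finger regulator of stem cells, was at 33.6 ± 20.3 normalized counts in WT and 228 ± 207 in Stat3β TG, and Pbx3, a cofactor of HOX proteins, at 5708 ± 2002 and 2829 ± 1052 (SD, n = 3 each). Among 16 stem and progenitor genes 9 were higher (camera adjusted p = 0.950), with Erg at 1784 ± 522 and 3024 ± 605 and Cd34 at 8127 ± 143 and 5594 ± 2226. Of 26 adhesion and homing molecules 19 were higher (0.211). The list held the integrin gene Itgax at 95.6 ± 30.6 and 303 ± 156 and the chemokine receptor gene Cxcr4 at 23095 ± 2522 and 16211 ± 3343. Primary granule genes were higher in 10 of 14 (0.530), and were called higher with the sex-linked term, against WT 2 alone (0.0450). The MLL-AF9 programme was called higher without both WT 2 and WT 3 (median 0.16, 0.0441).

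**Figure D4:**
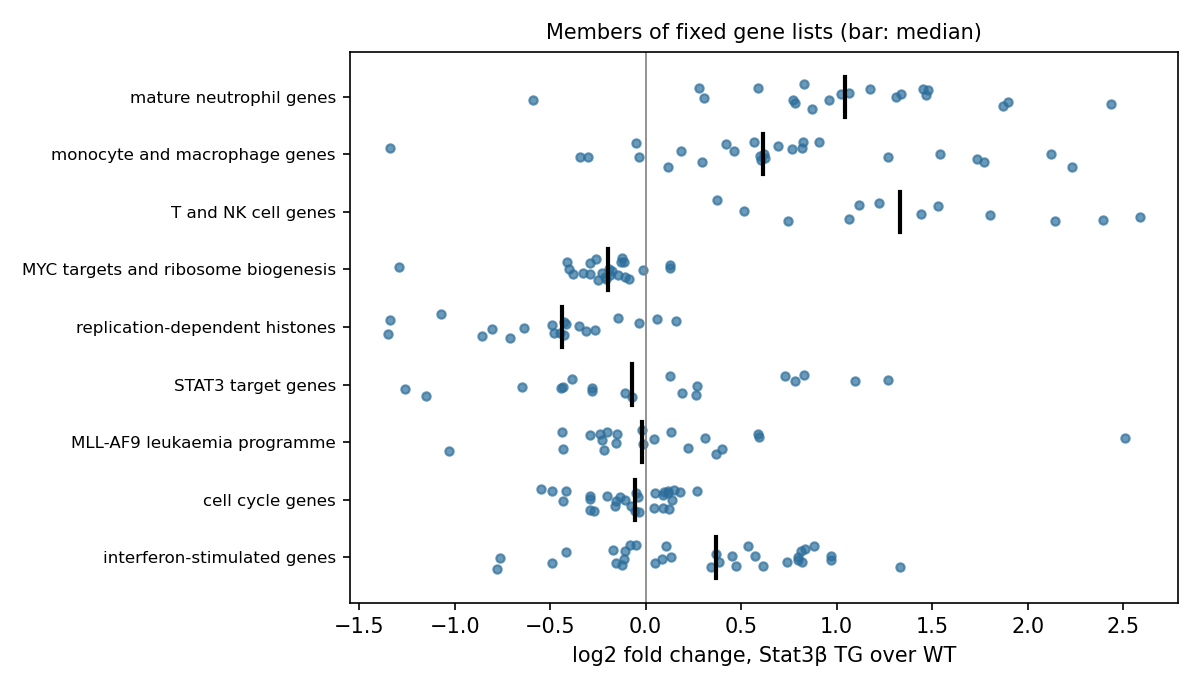
Log2 fold change of Stat3β TG over WT on the log2(normalized count + 1) scale for each tested member of 9 gene lists, with 1 point per gene and a bar at the list's median. The median is 1.04 for mature neutrophil genes, 0.61 for monocyte and macrophage genes and -0.44 for histones, and -0.07 for STAT3 targets.

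Metabolic and stress lists were not called in the fit with the group as the only term. Cholesterol synthesis genes were higher in 16 of 21, with a median log2 fold change of 0.24 (camera adjusted p = 0.141). They were called higher without WT 1 (0.00728) or Stat3β TG 3 (0.0495), and lower without both WT 2 and WT 3 (median -0.17, 0.0258). Glycolysis and hypoxia genes were higher in 12 of 23 with a median of 0.02 (0.565), which became -0.04 under quantile normalization. Ndrg1, a gene induced by hypoxia, was at 667 ± 403 normalized counts in WT and 1670 ± 467 in Stat3β TG (SD, n = 3 each). Immediate-early and dissociation stress genes were lower in 14 of 22 (camera adjusted p = 0.121), with Egr1 at 22821 ± 6842 and 8095 ± 5671. Egr2 fell when adjusted over the list alone (limma adjusted p = 0.0218), a call lost without WT 3, Stat3β TG 1 or Stat3β TG 3 and with the sex-linked term, where 0 members passed, and without both WT 2 and WT 3, where 2 others passed. The immediate-early list was called without Stat3β TG 2 (1.15e-05). Genes of the unfolded protein response were higher in 13 of 20 (0.141), the BCL2 family in 10 of 14 (0.565), p53 targets in 9 of 21 (0.282) and TGF-β response genes in 5 of 12 (0.329). The p53 list was called lower with the sex-linked term, against WT 2 alone (median -0.40, 0.0450). The glycolysis (0.0441) and TGF-β (0.0407) lists were called higher without both WT 2 and WT 3.

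Markers of T and NK cells, with a highest mean of 148 normalized counts over the 6 libraries, were the 1 list that camera called among the 9 lists of other cell types. All 12 tested T and NK cell genes were higher in Stat3β TG, with a median log2 fold change of 1.33 (camera adjusted p = 0.00519; adjusted p = 0.835 with an estimated correlation). Gzma, a granule protease, was at 78.4 ± 74.1 normalized counts in WT and 184 ± 70.6 in Stat3β TG, and Klrd1, an NK cell receptor, at 8.61 ± 11.6 and 31.5 ± 17.1 (SD, n = 3 each). The list mean was 5.43, 4.33 and 2.10 in WT and 5.73, 4.81 and 5.55 in Stat3β TG (exact permutation p = 0.2). The call was lost without WT 3 (median 0.31, camera adjusted p = 0.306) or Stat3β TG 1 (median 1.32, 0.0546), and among genes with a count of at least 50, where 5 members were tested (median 1.22, 0.158). With the sex-linked term, against WT 2 alone, it was 0.354, and without both WT 2 and WT 3 the median was -0.23 (0.427).

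The other marker lists were not called with all libraries. Megakaryocyte and platelet genes were higher in 7 of 8 (camera adjusted p = 0.114) and were called without WT 3 (0.0395). Eosinophil genes were higher in 3 of 6 (0.293) and were called without WT 2 (1.12e-05). In that list Prg2 fell when adjusted over the list alone (limma adjusted p = 0.0270), a call lost without WT 1, WT 3, Stat3β TG 2 or Stat3β TG 3, where 0 members passed, and with the sex-linked term. Epx, eosinophil peroxidase, was at 2045 normalized counts in WT 1 and between 25.9 and 106 in the others. Dendritic cell genes were higher in 5 of 8 (0.310), resident macrophage genes in 4 of 8 with a median of 0.16 and a mean of -0.08 (0.950), erythroid genes in 1 of 5 (0.530), mast cell and basophil genes in 4 of 6 (0.586) and stromal genes in 4 of 6 (0.633). The 4 tested B lineage genes were all higher (exact permutation p = 0.4). Of the 9 marker means, those of dendritic cells (difference 0.52) and megakaryocytes (0.70) reached the smallest exact permutation p of 0.1, and both were 0.45 after Benjamini-Hochberg adjustment over the 9. The sex-linked list had a camera adjusted p of 0.159, and was called without WT 2 (3.68e-12). Without WT 2 and WT 3 the dendritic cell (0.0108) and sex-linked lists were called higher and the eosinophil list lower (3.19e-11).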

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

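A term for the sex-linked pattern, reads thinned to equal totals, leaving out both WT 2 and WT 3, and every alternative of the DESeq2 count were chosen after seeing the data. Of 1688 pairs of a result and an alternative setting, 1590 were classed as unchanged. Most of these were log2 fold changes of single genes, 1080 and, with 1 library left out, another 393. No gene passed in the main fit, so staying on that side of the threshold was likely in advance. For genes and list medians, unchanged means the same direction and side of the threshold. For counts it means a similar size, and for marker means a small shift. The count of 0 genes by limma (771 at an unadjusted p under 0.05; edgeR 0, DESeq2 17) became 1 with sample weights, 2 with the sex-linked term and 8 without WT 2 and WT 3. Leaving out 1 library gave between 0 and 296 (WT 1). The DESeq2 count of 17 became 36 without a filter, 954 with the sex-linked term, 101 with the replicate block, 28 after thinning and 65 without WT 2 and WT 3. It ranged from 12 (without Stat3β TG 1) to 2012 (without WT 1) when 1 library was left out.

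Libraries of equal replicate number showed no clear pairing, with correlations of their deviations of 0.141, 0.0995 and -0.107. These correlations were not tested, so they cannot exclude a pairing. With the replicate block limma passed 0 genes (934 at an unadjusted p under 0.05), edgeR passed 0 (843), and camera called 6 lists. These were the 5 of the main fit and oxidative phosphorylation, which was lower. Of the 33 lists, where camera called 5, 0 were called with an estimated correlation and 0 by fry, whose smallest adjusted p was 0.612, while fry for change in either direction called 1, the histones. In all, 3 lists were called with the sex-linked term (1 of the 5), 15 without WT 2 and WT 3 (2 of the 5), and between 4 and 10 when 1 library was left out. Of 2 marker means at the smallest exact p, 1 stayed with all listed members.

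With the sex-linked term, which leaves WT 2 as the only WT library in the contrast, the log2 fold change was 0.43 for Prg3, 0.65 for Epx, -0.45 for Kdm5d, -0.69 for Ddx3y, -0.072 for Kmt2a and 0.20 for Kdm5c, each of the opposite sign. Kmt2a was at -0.003 with CPM values. Without WT 2 and WT 3 it was 0.25 for Stat3, -0.0051 for Fcnb, 0.074 for Shd and 1.91 for Il1r2, and the list medians were -0.046 for monocyte genes, 0.059 for MYC targets and -0.23 for T and NK cell genes. Leaving out 1 library gave log2 fold changes of -0.47 to 0.034 for Stat3, -2.68 to 0.16 for Epx, -0.049 to 1.98 for Ms4a3, -0.022 to 1.52 for Fcnb, -0.18 to 0.41 for Kmt2a, -0.11 to 0.54 for Mllt3, -1.84 to 0.39 for Il1r2 and -0.36 to 0.012 for Kdm5c. Fewer libraries also leave fewer degrees of freedom, and beyond that the cause was not tested. Depth limits genes below the floor of 1.69 to 4.22 normalized counts.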

Other observations

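All tests here except those of library depth and of the other splits were chosen after the result was seen. Some genes of the primary granule and progenitor list were lower in 1 library alone. Ms4a3, a marker of granulocyte and monocyte progenitors, was at 472 normalized counts in WT 2 and between 6931 and 7845 in the other 5 libraries. Fcnb, which encodes ficolin B, was at 1118 in WT 2 and between 7588 and 10357 in the others. With a term for the sex-linked pattern, which compares Stat3β TG with WT 2 alone and so restates these values, they were the 2 genes that limma passed, with log2 fold changes of 3.91 (adjusted p = 0.00132) and 3.04 (adjusted p = 0.0190). Over the alternatives of Ms4a3 the adjusted p ranged from 0.00132 to 0.9999, and over those of Fcnb from 0.0190 to 0.9999.

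The first pattern weighed is that 19 of 20 mature neutrophil genes were higher in Stat3β TG. Library depth was examined by thinning to equal totals, after which the median log2 change was 1.05, with an SD of 0.0151 for the shifts of the members. The number of reads as such therefore does not account for the shift. Thinning keeps the share of reads of each gene, so for genes with many reads this outcome was near certain. It does not bear on other differences between libraries that go with depth. Within WT the library with Y-linked reads, WT 2, had a median difference of -0.79 from the other 2, so the sex-linked pattern went against the direction seen in Stat3β TG, but 1 library cannot decide. Mature host cells left in the sort may contribute, a hypothesis that stays open with all but 1 of the members higher. The sort for Venus is meant to remove such cells, but its purity was not measured here. All 20 members were expressed in WT as well and 3 are in another list, and the most abundant were Chil3 at 107284 ± 76357 normalized counts in WT and 265967 ± 97794 in Stat3β TG, Ngp at 80172 ± 36274 and 113364 ± 32165, and S100a9 at 65445 ± 38264 and 125946 ± 23881 (SD, n = 3 each), while Il1r2 was the 1 member lower (log2 fold change -0.59, and 0.39 without WT 2).

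The second pattern is the split of the WT libraries by Xist and Y-linked genes. A swap between a WT and a Stat3β TG library was looked for, and 0 Stat3β TG libraries had more Xist than Y-linked reads. This cannot exclude a swap. An exchange of WT 2 with a Stat3β TG library, for example, would leave the count at 0. Loss of the Y chromosome is argued against, since the lowest Xist value among the libraries with few Y-linked reads was 51.1 times the highest among the others. Donor cells of both sexes could give this pattern. Y-linked genes in WT 1 and WT 3 summed to 0.613% and 0.749% of the mean of the other libraries. Xist in those other libraries was at most 1.90% of its mean in WT 1 and WT 3. The labels do not give the sex of the donors. The genes that escape X inactivation do not decide by themselves: 2 of 4 (Kdm6a and Eif2s3x, but not Kdm5c or Ddx3x) were higher in both WT 1 and WT 3 than in every other library. Of all genes 3.36% separated so, and 3 of 4 had been set as the bound. As no Stat3β TG library has the pattern of WT 1 and WT 3, a sex-linked difference cannot be fully told apart from the group.

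The third pattern is that Kmt2a and Mllt3, the mouse genes of the MLL and AF9 proteins, varied together over the 6 libraries. Pearson's r was 0.966 (exact two-sided permutation p = 0.00139) and Spearman's rho was 1 (exact permutation p = 0.00278), in the 1 pair examined, which was picked after its values were seen. Without Stat3β TG 2 and Stat3β TG 3, the libraries farthest from the median, r was 0.987. The correlation was at the 99.97 percentile of those of Kmt2a with all tested genes, and 4 of 12640 genes had a higher r, but this restates the observation by which the pair was picked. Reads of the fusion transcript counted in both genes are a candidate explanation that stays open, because fusion and endogenous transcripts were not separated, and no biological explanation was tested.

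The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. For the limma count they carry no information, since a real count of 0 is matched by any split, here by 10 of 10 with 0 genes as the highest other. The 771 genes at an unadjusted p under 0.05 compare with 1906 in the highest other split. At least as many came from 4 of the 10 splits, a count that includes the real grouping, as do those that follow. DESeq2 called 17 genes against 206 in the highest other, and 5 of the 10 splits gave at least as many. Camera called 5 lists against 15 in the highest other, and 10 of 10 splits gave at least as many, so no split called fewer lists than the real grouping. The splits with 1906 and 206 genes put WT 1 with Stat3β TG 1 and 3 against WT 2, WT 3 and Stat3β TG 2, which points to a structure of the samples.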
